A study of Mus musculus with 11 samples.

How the data were processed

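Total RNA was extracted with Trizol from sorted cells of C57BL/6J mice, labelled with biotin using an Affymetrix whole-transcript kit and hybridised to 11 arrays, 1 per sample. The deposited values are log2 intensities that the authors made by RMA, per the labels, which corrects background, normalizes quantiles between arrays and summarises each probe set; the version of RMA, the chip definition and the genome build are not given in the sources used here. The log2 scale was read from the values, which run from about 2 to 14 on every array with medians between 6.02 and 6.12. Groups followed the sample titles: 2 arrays each of HSC, LMPP, CLP, ETP and DN3 and 1 of DN2. The descriptions of the thymic samples name bone marrow, whereas their tissue labels and the design text name thymus, and the tissue label was used. The labels number the replicates without stating whether they came from separate animals or pools, so the p-values may measure only technical spread.

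The table held 35556 probe sets. Of these, 21789 had 1 gene symbol in the annotation given, 1621 had several and 12146 had none; only those with 1 symbol were used, and 21698 of them had an Entrez ID in the RefSeq gene table. Of the 999 genes with more than 1 probe set the one with the highest mean over the 11 arrays was used, which left 19938 genes, and no gene was left out for low intensity. Genes without a probe set of their own in that annotation were not analysed here. Positions are not printed because no build is given; the RefSeq table (assembly GRCm38.p6) served only for names and for which genes are neighbours.

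Differential expression was tested with limma 3.58.1 in R 4.3.3 on the log2 values. One fit held 6 group means over the 11 arrays, with 5 residual degrees of freedom and a spread moderated across genes, so DN2, with its 1 array, was assumed to vary like the other populations. From it came the F test over the 6 populations and 7 comparisons of 2 populations, each two-sided and adjusted by Benjamini-Hochberg over the 19938 genes; a gene was called at adjusted p under 0.05. Thymus and bone marrow were compared in a separate fit with 2 groups of 5 and 6 arrays. Genes highest in a population were those whose 4 contrasts with the other replicated populations were all positive, with the largest of the 4 p-values adjusted over all genes. Values are means ± SD over arrays and folds come from the difference of means; no separate error is given for a fold. Tables were handled in Python 3.11.15 with pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

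A set of 25 gene lists, written from general knowledge of blood formation and early T cell development, was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 25 lists in each comparison. They cover HSC-associated genes, lymphoid priming, B lineage, T lineage, Notch-responsive genes, progenitor transcription factors and receptors, myeloid, erythroid and megakaryocyte, natural killer and innate lymphoid, dendritic cell and MHC class II, later thymocyte and mature T cell, macrophage, stromal, epithelial and endothelial, S phase, G2 and M phase, cell cycle inhibitors and quiescence, immediate early and stress, homing receptors and adhesion, V(D)J recombination and end joining, E protein and Id, Hox genes and cofactors, imprinted, interferon-stimulated, glycolysis, and DNA methylation and Polycomb genes. Some genes stand in several lists. Each list test was repeated with the correlation estimated from the data and with fry, which asks whether a set moves on balance without comparing it with other genes. Of 200 list tests (25 lists in 8 comparisons) the median, the mean and the test differed in sign in 28, and 0 of those 28 passed camera.

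The genes named in the text follow a rule: per comparison the 6 highest and 6 lowest called fold changes without overlap between arrays of the groups, leaving out predicted genes, receptor segments, histones and olfactory genes; per list up to 4 called members, or the member that moved most where none was called; a panel of 22 lineage genes, 20 of them measured; and per population the 6 highest genes of its own set by margin. Not all genes of the rule are named. The groups, comparisons, tests, lists, naming rule and alternatives were chosen before the data were examined, except for the tests, the mast cell list and the genes named in the closing part as chosen later.

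The alternatives were 2 filters on dim genes (keeping 13292 and 11062 genes), quantile normalization once more, centring of arrays on their medians, the mean of a gene's probe sets, an intensity trend with a robust prior, array weights, the replicate number as a block, thresholds of adjusted p under 0.01 and of at least 2-fold, fits of the 2 groups alone where both had 2 arrays, leaving out each array, and for the tissues a contrast of 6 means and a random block of population.

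The fit was tested on simulated data with the same group sizes, in which 200 of 19938 genes were given changes of 0.5, 1 or 2 on the log2 scale. Changes of 2 were called in 100% of cases in each comparison. Changes of 1 were called in 94% (LMPP against HSC), 95.5% (CLP against LMPP, ETP against LMPP and ETP against CLP), 86.6% (DN2 against ETP), 82.1% (DN3 against DN2), 98.5% (DN3 against ETP) and 97% (tissues), and changes of 0.5 in 4.48% to 20.9% of cases between populations and 55.2% between tissues. Between 3 and 14 unchanged genes were called in a comparison. For the tissues the simulated arrays varied independently, with no differences between populations, so the tissue rates do not carry over to the real arrays. In every comparison the noise was independent and normal, with the moderated spread of each gene. The rates between populations hold for such noise and 200 changed genes, and may differ on the real arrays.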

Results

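Transcript levels were measured on 11 Affymetrix arrays in 6 sorted populations of blood-forming and early T lineage cells from C57BL/6J mice. Blood stem cells (HSC), multipotent progenitors primed towards lymphoid fates (LMPP) and progenitors shared by the lymphoid lineages (CLP) came from bone marrow, with 2 arrays each. Early thymic precursors (ETP, 2 arrays), double negative 2 cells (DN2, 1 array) and double negative 3 cells (DN3, 2 arrays) came from thymus. All values are log2 intensities, and the median of an array lay between 6.02 and 6.12. The number of arrays limits the precision of every value, and DN2 has no replicate. The sort gates are not given in the sources used here. A gene that served as a sort marker differs between the populations by the sort itself. Il2ra, Kit, Cd44, Flt3 and Il7r commonly serve as such markers for these populations. Counts and tests of gene lists that hold such a gene may be set in part by the sort too. Folds are ratios of intensities; no detection calls were used here, and where the lower level lies near background the fold is a lower bound for the ratio of transcripts.

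The first question was how expression differed over the 6 populations. Flt3, a cytokine receptor of early progenitors, stood at 7.25 ± 0.18 in HSC, 10.61 ± 0.19 in LMPP, 10.58 ± 0.11 in CLP and 8.61 ± 0.077 in ETP (SD, n = 2 each), at 5.23 in DN2 and at 5.09 ± 0.15 in DN3. Il2ra, the alpha chain of the interleukin 2 receptor by which DN2 and DN3 thymocytes are commonly sorted, stood at 7.32 ± 0.51 in ETP, 11.40 in DN2 and 11.27 ± 0.049 in DN3, against 4.26 ± 0.27 in LMPP. Ebf1, a transcription factor of the B lineage, stood at 9.27 ± 0.074 in CLP and at 5.09 ± 0.49 in LMPP, and Rag1, a subunit of the recombinase of antigen receptor genes, stood at 10.98 ± 0.17 in CLP and 11.54 ± 0.13 in DN3. In the limma F test the number of genes differing among the 6 populations was 2430 of 19938 (12.2%). That count was 1543 without DN3 replicate 1 and 1499 without DN3 replicate 2.

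**Figure D1:**
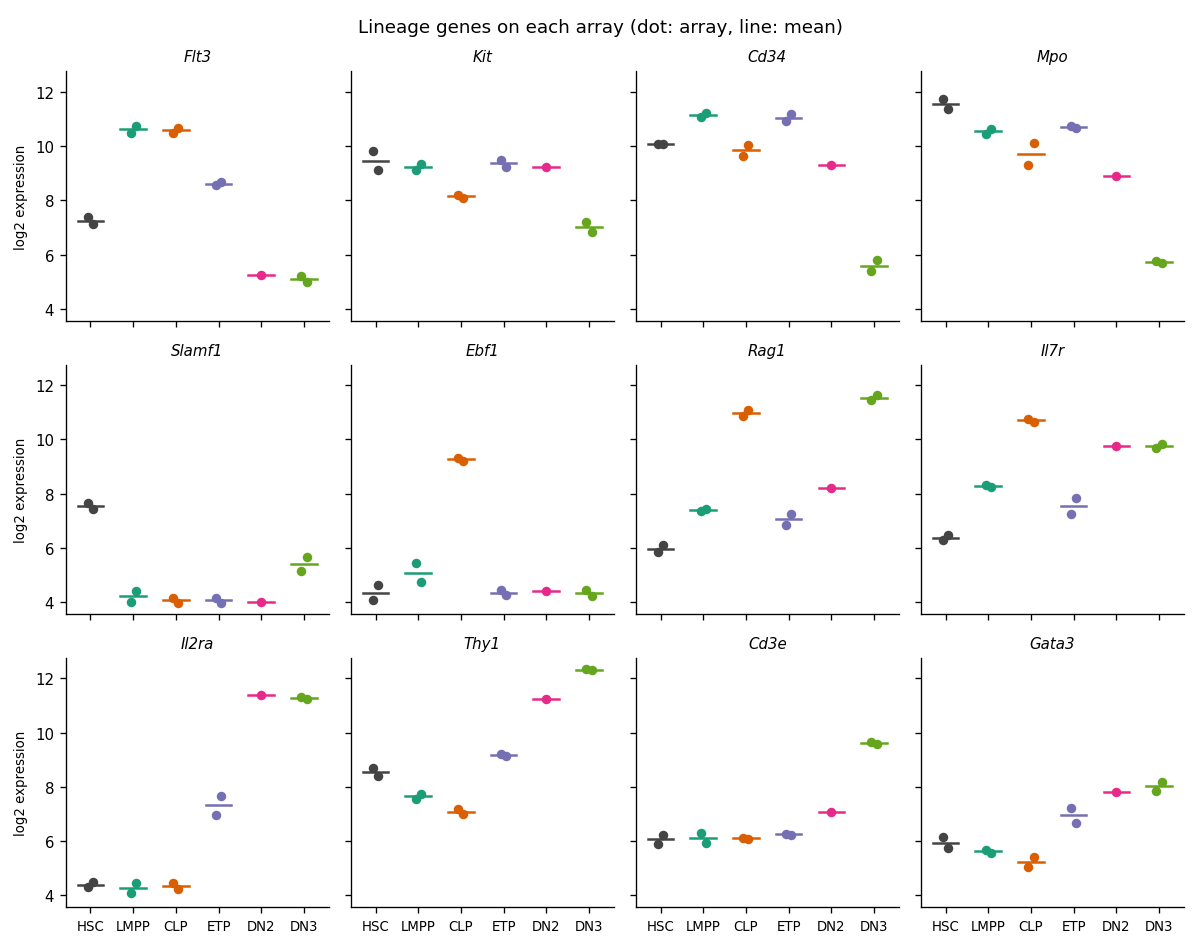
Log2 expression (y axis) of 12 lineage genes in the 6 populations (x axis); each dot is 1 array and each line the mean of a population. Flt3 was lower in DN2 (5.23) and DN3 (5.09) than in LMPP (10.61), while Thy1 stood at 7.09 in CLP and 12.33 in DN3.

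Principal components of the 11 arrays kept the replicates of each population next to each other. The first component (39.2% of the variance) placed the DN3 arrays at 44.09 and 46.44 and DN2 at 21.09, and the second (20.5%) placed the HSC arrays at 37.56 and 27.12. Across genes, which are not independent replicates, replicate arrays correlated with r from 0.988 in HSC to 0.996 in DN3. In each population this exceeded the highest r with another population, but narrowly in LMPP (0.9911 against 0.9885) and CLP (0.9905 against 0.9885). The value of 0.9885 between populations was above the 0.9882 between the HSC replicates. The DN2 array had its highest r with ETP replicate 2 (0.988), and its r with DN3 replicate 1 was 0.986.

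**Figure D2:**
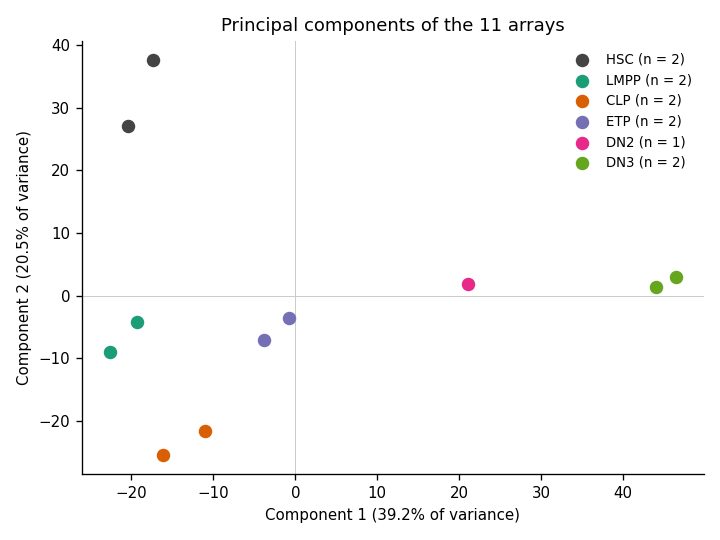
Scores of the 11 arrays on principal component 1 (x axis, 39.2% of the variance) and principal component 2 (y axis, 20.5% of the variance); each dot is 1 array, coloured by population. DN3 lies at 44.09 and 46.44 on component 1, and HSC at 37.56 and 27.12 on component 2.

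The comparison of LMPP with HSC addressed the first lymphoid-primed step in marrow. Genes of lymphoid priming were higher in LMPP: Dntt, the polymerase that adds nucleotides at antigen receptor joints, reached 11.99 ± 0.018 against 8.10 ± 0.31 in HSC (SD, n = 2 each; 14.8-fold, adjusted p = 7.93e-07), and Flt3 was 10.3-fold higher (adjusted p = 1.29e-06). Rag2, the partner of Rag1, was 7.62-fold higher, Il7r, the receptor chain for interleukin 7, 3.73-fold and Ccr9, a thymus homing receptor, 3.01-fold. Pf4, a platelet chemokine, stood at 5.53 ± 0.42 in LMPP against 10.96 ± 0.023 (43.2-fold lower, adjusted p = 2.21e-07), Car1, a red cell carbonic anhydrase, was 49.7-fold lower, and Elane, a neutrophil granule protease, 10.6-fold lower. Slamf1, a surface marker of HSC, was 10.1-fold lower (4.21 ± 0.28 against 7.54 ± 0.18).

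Of 23 measured lymphoid priming genes 12 rose and 11 were not called (16 rose when adjusted over the list alone; 7 rose without LMPP replicate 2), with a list adjusted p = 1.79e-21 by camera. Of 30 HSC-associated genes 15 fell and 1, Vldlr, rose (18 fell and 1 rose adjusted over the list alone; adjusted p = 2.62e-16); 6 fell without HSC replicate 1, LMPP replicate 1 or LMPP replicate 2, and Vldlr was not called without HSC replicate 2 or LMPP replicate 2. Of 23 erythroid and megakaryocyte genes 10 fell (15 adjusted over the list alone; adjusted p = 3.29e-12), and 4 fell without HSC replicate 1, 5 without LMPP replicate 1 and 4 without LMPP replicate 2. Of 20 dendritic cell and MHC class II genes 4 rose (5 adjusted over the list alone; adjusted p = 9.86e-08); Flt3, Ccr9 and Tcf4, an E protein that rose 1.84-fold, are among them. These 4 lists held with an estimated correlation, at adjusted p = 0.0177, 0.0107, 0.0286 and 0.0302 in that order.

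Myeloid genes moved both ways, since 8 of 28 fell and 2 rose (8 and 4 adjusted over the list alone). Elane and Ms4a3 (27.7-fold lower), a gene of granulocyte and monocyte progenitors, fell, and Cd33, a sialic acid binding receptor, rose 4.1-fold. The list passed camera at adjusted p = 0.00607 but not with an estimated correlation (adjusted p = 0.487 with an estimated correlation), nor without HSC replicate 2 (adjusted p = 0.102). Without LMPP replicate 2 the number that fell was 4, and 1 rose without HSC replicate 1, either LMPP replicate or either DN3 replicate. The G2 and M phase list rose at adjusted p = 1.08e-12 (adjusted p = 0.244 with an estimated correlation). Of its 29 genes 17 rose adjusted over the list alone and 5 over all genes, among them Kif23, a motor protein of cell division (2.28-fold). Those 5 became 3 without either HSC replicate, LMPP replicate 1 or either ETP replicate, 2 without either DN3 replicate and 1 without LMPP replicate 2. In all 586 genes passed the test, 246 higher and 340 lower in LMPP, and 249 of them differed at least 2-fold. The count was 369 without HSC replicate 1, 327 without LMPP replicate 1 and 310 without LMPP replicate 2.

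**Figure D3:**
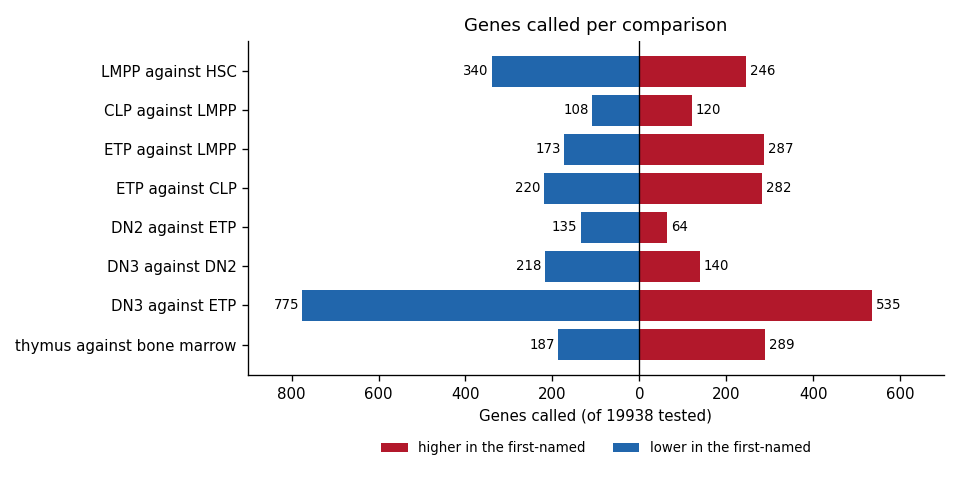
Number of genes called at adjusted p under 0.05 of 19938 tested (x axis, counts to either side of 0) in each comparison (y axis); red bars are genes higher and blue bars genes lower in the population or tissue named first. DN3 against ETP has the longest bars, with 535 genes higher and 775 lower.

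The comparison of CLP with LMPP addressed lymphoid restriction in marrow. Ebf1 stood at 9.27 ± 0.074 against 5.09 ± 0.49 in LMPP (SD, n = 2 each; 18.2-fold higher, adjusted p = 1.67e-05), and Rag1 at 10.98 ± 0.17 against 7.39 ± 0.054 (adjusted p = 7.21e-06). Ly6d, a surface marker of B-biased CLP, was 13.6-fold higher, Blnk, an adaptor of B cell receptor signalling, 10.6-fold and Il7r 5.38-fold. Genes lower in CLP included Hlf, a transcription factor of stem cells (3.98-fold), Car2, a carbonic anhydrase (4.93-fold), Cd63, a granule and lysosome membrane protein (4.21-fold), and the neutrophil proteases Ctsg (3.96-fold) and Prtn3 (2.48-fold). Flt3 was not called (10.58 against 10.61), and Dntt stood at 12.50 ± 0.044 against 11.99 ± 0.018 (adjusted p = 0.232).

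Of 24 B lineage genes 8 rose and none fell (15 adjusted over the list alone; camera adjusted p = 2.66e-22); the 8 were 4 without LMPP replicate 2 and 5 without CLP replicate 1. Of 23 lymphoid priming genes 6 rose (10 adjusted over the list alone; adjusted p = 1.18e-13), and of 30 HSC-associated genes 5 fell (7 adjusted over the list alone; adjusted p = 8.94e-07), among them Hlf and Vldlr (2.98-fold). These 3 lists held with an estimated correlation, at adjusted p = 0.035 each. Of 23 natural killer and innate lymphoid genes 3 rose (6 adjusted over the list alone; adjusted p = 5.4e-08, and adjusted p = 0.0972 with an estimated correlation); Klrd1, a natural killer receptor chain, rose 5.74-fold and Fcer1g, an adaptor of Fc receptors, 2.19-fold. Of 15 V(D)J recombination and end joining genes 3 rose (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.00029, and adjusted p = 0.187 with an estimated correlation). Siglech, a marker of plasmacytoid dendritic cells, was 4.61-fold higher (8.05 ± 0.43 against 5.85 ± 0.0049).

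Of 21 interferon-stimulated genes 3 fell (8 adjusted over the list alone; adjusted p = 7.42e-06, and adjusted p = 0.111 with an estimated correlation), with Ifitm1, a membrane protein, 2.13-fold lower; 1 fell without either LMPP replicate or either CLP replicate. The G2 and M phase list fell at adjusted p = 7.04e-18 (adjusted p = 0.111 with an estimated correlation), with 15 of its 29 genes lower adjusted over the list alone and 2 over all genes. Those 2 became 1 without either HSC or either ETP replicate and none without either LMPP, CLP or DN3 replicate. In all 228 genes passed limma, 120 higher and 108 lower in CLP, and quantile normalization once more turned the balance to 131 higher and 140 lower. The count was 139 without LMPP replicate 1, 98 without LMPP replicate 2, 125 without CLP replicate 1 and 135 without CLP replicate 2.

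The comparison of ETP with LMPP set the earliest thymic population against multipotent progenitors of marrow. Cpa3, a mast cell carboxypeptidase, stood at 9.99 ± 0.32 in ETP (SD, n = 2 in each population), 31.8-fold above LMPP (limma adjusted p = 3.48e-06). Its level in HSC was about as high (10.11 ± 0.24), so Cpa3 was not particular to ETP. Fasl, the ligand of a death receptor, was 13.0-fold higher in ETP than in LMPP, and H2-Aa, an MHC class II chain, 9.38-fold. Il2ra was 8.33-fold higher (7.32 ± 0.51 against 4.26 ± 0.27), Hes1, a target gene of Notch, 4.49-fold (8.23 ± 0.056 against 6.06 ± 0.14; adjusted p = 1.41e-05) and Thy1, a surface protein of T cells, 2.89-fold. Wfdc17, a small secreted protein of myeloid cells, was 35.7-fold lower, Flt3 4.02-fold and Jun, a subunit of the AP-1 transcription factor, 7.08-fold (6.87 ± 0.29 against 9.70 ± 0.056). Il7r stood at 7.55 ± 0.40 against 8.28 ± 0.070 (adjusted p = 0.0587), and Kit, the stem cell factor receptor, at 9.37 ± 0.18 against 9.23 ± 0.14.

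Of 31 T lineage genes 10 rose and none fell (14 adjusted over the list alone; camera adjusted p = 3.4e-10, and adjusted p = 0.0572 with an estimated correlation). Cd3g, a chain of the T cell receptor complex, rose 8.08-fold, and its log2 change of 3.02 was 3.90 without ETP replicate 1 and 2.13 without ETP replicate 2. Of 23 immediate early and stress genes 9 fell and none rose (16 adjusted over the list alone; adjusted p = 3.24e-18, and adjusted p = 0.0796 with an estimated correlation), including Fos, the partner of Jun (3.88-fold). Of 18 Notch-responsive genes 4 rose (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.0105, and adjusted p = 0.158 with an estimated correlation); 2 rose without LMPP replicate 2 or ETP replicate 1, and the list was then at adjusted p = 0.0792 and 0.0545. Its median of 0.00803 changed sign when quantiles were normalized once more. Of 23 natural killer and innate lymphoid genes 5 rose and 1, Nfil3, fell (6 and 1 adjusted over the list alone; adjusted p = 0.000552, and adjusted p = 0.242 with an estimated correlation); Cd160, a receptor of cytotoxic cells, rose 5.71-fold, and Gzma, a granzyme, 4.47-fold. Of 28 myeloid genes 4 rose and 2 fell (9 and 2 adjusted over the list alone), with S100a8, a calcium-binding protein of neutrophils, 8.34-fold and Ms4a3 9.99-fold higher, and Csf3r, the receptor for granulocyte colony-stimulating factor, 2.37-fold lower. That list passed at adjusted p = 0.0246 but not with an estimated correlation (adjusted p = 0.552 with an estimated correlation), nor without LMPP replicate 2 (0.182) or ETP replicate 2 (0.141). Without LMPP replicate 1 or ETP replicate 2 only 2 myeloid genes rose, and 1 fell without either LMPP replicate or either ETP replicate.

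Of 20 dendritic cell and MHC class II genes 4 rose and 2 fell (the same counts adjusted over the list alone), and the list was not called (adjusted p = 0.883). The G2 and M phase list fell at adjusted p = 2.51e-16 (adjusted p = 0.158 with an estimated correlation), with 21 of 29 genes lower adjusted over the list alone and 4 over all genes. Those 4 became 1 without LMPP replicate 2 or either ETP replicate, and 2 without either DN3 replicate. Cenpf, a kinetochore protein, fell 1.97-fold. In all 460 genes passed limma, 287 higher and 173 lower in ETP, and quantile normalization once more gave 263 higher and 260 lower. The count was 258 without LMPP replicate 1, 262 without LMPP replicate 2, 284 without ETP replicate 1 and 228 without ETP replicate 2.

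**Figure D4:**
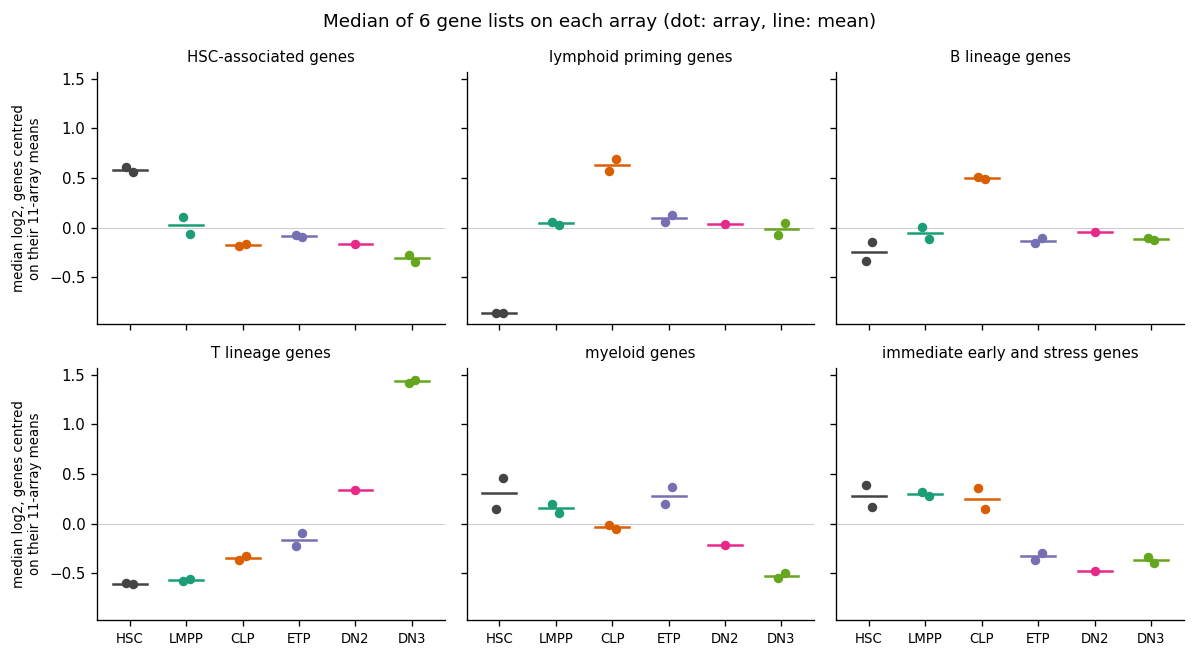
Median log2 value of 6 gene lists on each array (y axis, each gene centred on its mean over the 11 arrays) in the 6 populations (x axis); each dot is 1 array and each line the mean of a population. For the immediate early and stress genes the 5 thymic arrays lie between -0.476 and -0.298 and the 6 marrow arrays between 0.142 and 0.39.

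The comparison of ETP with CLP set the same thymic population against the lymphoid progenitor of marrow. Ebf1 stood at 4.35 ± 0.12 against 9.27 ± 0.074 (SD, n = 2 each; 30.3-fold lower, adjusted p = 2.08e-06), Rag1 and Blnk were each 15.2-fold lower, and Il7r was 8.91-fold lower (7.55 ± 0.40 against 10.71 ± 0.059). Mpeg1, a pore-forming protein of phagocytes and B cells, was 21.1-fold lower, Siglech 5.72-fold and Flt3 3.94-fold. Higher in ETP were Cpa3 (27.6-fold), Clec4e, a lectin receptor of myeloid cells (11.6-fold), H2-Aa (11.4-fold) and Cd74, the invariant chain of MHC class II (2.59-fold). The T lineage regulator Gata3 was 3.31-fold higher (6.95 ± 0.39 against 5.22 ± 0.27; adjusted p = 0.00144), Thy1 4.24-fold and Hes1 3.0-fold. Mpo, the peroxidase of neutrophil granules, stood at 10.71 ± 0.062 against 9.72 ± 0.57 and missed the threshold (adjusted p = 0.0512).

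Of 24 B lineage genes 9 fell and none rose (14 adjusted over the list alone; camera adjusted p = 8.74e-19, and adjusted p = 0.109 with an estimated correlation), and 5 fell without ETP replicate 2. Of 15 V(D)J recombination and end joining genes 3 fell (3 rose and 3 fell adjusted over the list alone), and the list was not called (adjusted p = 0.414); 1 also rose without either HSC replicate or ETP replicate 1. Of 31 T lineage genes 9 rose and 4 fell (14 and 5 adjusted over the list alone; adjusted p = 0.000817, and adjusted p = 0.117 with an estimated correlation); Rag1 and Ly6d (7.55-fold lower), which B lineage progenitors express too, are among the 4. Of 23 lymphoid priming genes 8 fell and 1 rose (10 and 3 adjusted over the list alone; adjusted p = 5.38e-06, and adjusted p = 0.117 with an estimated correlation), the riser being Ltb, a lymphotoxin chain. Of 28 myeloid genes 6 rose and 2 fell (11 and 2 adjusted over the list alone; adjusted p = 2.71e-06, and adjusted p = 0.166 with an estimated correlation); S100a8 rose 8.17-fold and Fcer1g fell 2.28-fold, and 1 fell without any 1 of the LMPP, CLP, ETP and DN3 arrays. Of 18 Notch-responsive genes 3 rose (5 adjusted over the list alone; adjusted p = 0.00269, and adjusted p = 0.117 with an estimated correlation). Of 23 immediate early and stress genes 8 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 5.61e-16, and adjusted p = 0.109 with an estimated correlation), with Jun 6.95-fold and Fos 3.76-fold lower; 4 fell without CLP replicate 1 or ETP replicate 1, and none rose without ETP replicate 2. In all 502 genes passed limma, 282 higher and 220 lower in ETP. The count was 310 without CLP replicate 1, 330 without CLP replicate 2, 278 without ETP replicate 1 and 248 without ETP replicate 2.

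The comparison of DN2 with ETP covered the first step within the thymus and rested on a single DN2 array. Themis, a protein of T cell receptor signalling in thymocytes, stood at 8.21 against 5.11 ± 0.25 in ETP (SD, n = 2; 8.59-fold higher, adjusted p = 0.000212), and Thy1 was 4.15-fold higher (11.23 against 9.18 ± 0.056) and Il7r 4.67-fold. Il2ra stood at 11.40 against 7.32 ± 0.51 (16.9-fold, adjusted p = 6.2e-05), a difference that a sort on it would fix. Cd3g was 12.5-fold higher, with a log2 change of 3.65 that was 2.76 without ETP replicate 1 and 4.53 without ETP replicate 2. Lig4, the ligase of end joining, was 3.07-fold higher and Gzma 5.43-fold. Flt3 was 10.4-fold lower (5.23 against 8.61 ± 0.077; adjusted p = 1.28e-05), H2-Aa 10.2-fold, Ms4a3 9.72-fold, and Ctss, a lysosomal protease of antigen-presenting cells, 7.65-fold. Meis1, a homeobox gene of stem cells, was 4.33-fold lower, Lmo2, a transcriptional adaptor of progenitors, 3.8-fold and Cd34, a progenitor surface protein, 3.29-fold. Gata3 (7.82 against 6.95), Bcl11b, a T lineage commitment factor (6.97 against 6.15), Cd3e (7.08 against 6.25) and Spi1, a myeloid transcription factor (6.69 against 7.60), were not called.

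Of 31 T lineage genes 10, Il2ra among them, rose and 1, Cd7, fell (18 and 1 adjusted over the list alone; camera adjusted p = 7.66e-18), and of 20 dendritic cell and MHC class II genes 6 fell (6 adjusted over the list alone; adjusted p = 1.11e-10). These 2 lists held with an estimated correlation, at adjusted p = 0.0141 and 0.0282. Of 23 progenitor transcription factors and receptors 7 fell (11 adjusted over the list alone; adjusted p = 3.64e-15, and adjusted p = 0.0606 with an estimated correlation). Of 28 myeloid genes 9 fell (11 fell and 1 rose adjusted over the list alone; adjusted p = 3.11e-16, and adjusted p = 0.0606 with an estimated correlation), Ms4a3 and Anxa1, a phospholipid-binding protein (4.31-fold), among them; 5 fell without ETP replicate 1 and 3 without ETP replicate 2. The S phase list rose at adjusted p = 1.6e-16 (adjusted p = 0.102 with an estimated correlation), with 5 of 29 genes higher adjusted over the list alone and 1 over all genes, which was not called without either ETP replicate. The interferon-stimulated list fell at adjusted p = 1.16e-10 (adjusted p = 0.0606 with an estimated correlation), with 8 of 21 genes lower adjusted over the list alone and 1 over all genes (3 without ETP replicate 1, none without ETP replicate 2). In all 199 genes passed limma, 64 higher and 135 lower in DN2, and 150 of them differed at least 2-fold. The count was 92 without ETP replicate 2.

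The comparison of DN3 with DN2 covered the second step within the thymus, again with the single DN2 array. Cd3d stood at 12.06 ± 0.022 (SD, n = 2) against 8.10 (15.5-fold higher, adjusted p = 0.000273), Cd3e at 9.62 ± 0.034 against 7.08 (5.82-fold) and Rag1 at 11.54 ± 0.13 against 8.21 (adjusted p = 1.22e-05). Ptcra, the surrogate alpha chain of the pre-T cell receptor, was 3.18-fold higher, Sh2d1a, an adaptor of T cell signalling, 15.5-fold, Cd28, a costimulatory receptor, 8.78-fold and Ccr9 6.71-fold (7.62 ± 0.31 against 4.87). Cd34 was 13.3-fold lower (5.59 ± 0.28 against 9.32), Tyrobp, an adaptor of myeloid and natural killer receptors, 21.5-fold, Hhex, a progenitor homeobox factor, 12.7-fold, and Mpo 8.92-fold. Kit was 4.66-fold lower, Cd44, an adhesion receptor lost between these stages, 3.56-fold, and Ifitm1 13.7-fold. Il2ra stood at 11.27 ± 0.049 against 11.40, and Spi1 at 5.83 ± 0.00023 against 6.69; neither was called.

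Of 31 T lineage genes 16 rose and 1, Cd7, fell (22 and 2 adjusted over the list alone; camera adjusted p = 7.87e-29), and this list held with an estimated correlation (adjusted p = 0.00447). Of 15 V(D)J recombination and end joining genes 2 rose (5 adjusted over the list alone; adjusted p = 0.000112, and adjusted p = 0.216 with an estimated correlation), and 1 rose without either DN3 replicate. The adjusted p of Cd7 was 0.0244, and Cd7 was not called without either DN3 replicate. Of 23 progenitor transcription factors and receptors 10 fell (16 adjusted over the list alone; adjusted p = 1.09e-22, and adjusted p = 0.0625 with an estimated correlation), and 6 fell without DN3 replicate 2. Of 28 myeloid genes 6 fell (7 adjusted over the list alone; adjusted p = 5.08e-07, and adjusted p = 0.216 with an estimated correlation), and 3 fell without DN3 replicate 1. Of 23 lymphoid priming genes 5 rose and 1, Tyrobp, fell (8 and 2 adjusted over the list alone; adjusted p = 0.00509, and adjusted p = 0.293 with an estimated correlation). Of 23 natural killer and innate lymphoid genes 4 fell (7 fell and 1 rose adjusted over the list alone; adjusted p = 0.000107, and adjusted p = 0.216 with an estimated correlation), with Fcer1g 4.99-fold and Cd160 2.87-fold lower. In all 358 genes passed limma, 140 higher and 218 lower in DN3, and 246 of them differed at least 2-fold. The count was 197 without DN3 replicate 1 and 181 without DN3 replicate 2.

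The comparison of DN3 with ETP spanned the thymic steps with 2 arrays on each side. Themis stood at 10.10 ± 0.027 against 5.11 ± 0.25 (SD, n = 2 each; 31.8-fold, adjusted p = 1.32e-07), Rag1 was 22.4-fold higher in DN3, Il2ra 15.4-fold, Cd3e 10.3-fold (9.62 ± 0.034 against 6.25 ± 0.015) and Thy1 8.88-fold. Cd3d was 59.9-fold higher, with a log2 change of 5.90 that was 5.26 without ETP replicate 1 and 6.55 without ETP replicate 2. Bcl11b was 2.05-fold higher (7.18 ± 0.10 against 6.15 ± 0.021; adjusted p = 0.00264), Ptcra 3.0-fold, Tcf12, an E protein, 3.2-fold and Id3, an inhibitor of E proteins, 2.48-fold. Cd34 was 43.8-fold lower (5.59 ± 0.28 against 11.04 ± 0.18; adjusted p = 5.73e-08), Mpo 31.6-fold, S100a4, a calcium-binding protein, 25.3-fold, and Hhex 22.8-fold. Spi1 was 3.42-fold lower (5.83 ± 0.00023 against 7.60 ± 0.28), Flt3 11.4-fold, Kit 5.08-fold, Meis1 8.25-fold and Lmo2 7.56-fold.

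Of 31 T lineage genes 25 rose and 1, Cd7, fell (26 and 3 adjusted over the list alone; camera adjusted p = 2.41e-34, and adjusted p = 0.00292 with an estimated correlation); Cd7, a surface protein of early T and natural killer progenitors, fell 7.25-fold. Of 23 progenitor transcription factors and receptors 16 fell (19 adjusted over the list alone) and of 28 myeloid genes 16 fell (18 adjusted over the list alone), and no member of either list rose; their adjusted p was 0.037 and 0.0376 with an estimated correlation. Of 20 dendritic cell and MHC class II genes 7 fell and 1, Ccr9, rose (8 and 1 adjusted over the list alone; adjusted p = 0.0404 with an estimated correlation); Ccr9 was not called without ETP replicate 1 or DN3 replicate 2. Of 21 interferon-stimulated genes 10 fell (12 adjusted over the list alone; adjusted p = 0.0404 with an estimated correlation), Ifitm1 15.8-fold and Ifitm3 5.62-fold, and 6 fell without ETP replicate 2 or DN3 replicate 2. Of 23 natural killer and innate lymphoid genes 9 fell, Il18rap, a receptor chain for interleukin 18, by 9.11-fold, and 1, Gzma, rose 17.1-fold (11 and 1 adjusted over the list alone; adjusted p = 1.76e-08, and adjusted p = 0.0718 with an estimated correlation). Of 18 Notch-responsive genes 5 rose and 1 fell (7 and 2 adjusted over the list alone; adjusted p = 0.00215, and adjusted p = 0.093 with an estimated correlation); 3 rose without ETP replicate 1 and 2 without ETP replicate 2 or DN3 replicate 2, and none fell without ETP replicate 1 or either DN3 replicate. In all 1310 genes passed limma, 535 higher and 775 lower in DN3. The count was 805 without ETP replicate 1, 849 without ETP replicate 2, 760 without DN3 replicate 1 and 695 without DN3 replicate 2.

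The comparison of thymus against bone marrow (5 and 6 arrays) took differences between populations of a tissue as spread. It counted the arrays of a population as independent, although each tissue has only 3 populations, so its p-values may be too small. Tissue goes with developmental stage here, so the effects of tissue and stage cannot be separated. Jun was lower in thymus (6.92 ± 0.17, n = 5, against 9.73 ± 0.13, n = 6; SD, 6.97-fold, adjusted p = 2.22e-08), as were Zfp36, an immediate early regulator of mRNA decay (4.39-fold), Plk2, an immediate early kinase (6.83-fold), and Cd69, an early activation marker (8.63-fold). Hes1 was higher in thymus (8.30 ± 0.099 against 6.17 ± 0.40; 4.39-fold, adjusted p = 0.000195), as were Gata3 (3.87-fold), Scin, an actin-severing protein (10.5-fold), and Trat1, an adaptor of the T cell receptor (14.4-fold). Il2ra was 41.7-fold higher, with a log2 change of 5.38 that was 6.07 without ETP replicate 1. Cd3e (7.76 ± 1.7 against 6.10 ± 0.17), Flt3 (6.53 ± 1.9 against 9.48 ± 1.7) and Cd34 (8.52 ± 2.8 against 10.36 ± 0.64) were not called.

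Of 23 immediate early and stress genes 12 fell in thymus and none rose (18 adjusted over the list alone; camera adjusted p = 1.88e-18), and this list held with an estimated correlation (adjusted p = 0.000644). Of 31 T lineage genes 7 rose (16 adjusted over the list alone; adjusted p = 1.61e-16, and adjusted p = 0.0947 with an estimated correlation), and 11 rose without ETP replicate 1. Of 18 Notch-responsive genes 4 rose (5 adjusted over the list alone; adjusted p = 0.0001, and adjusted p = 0.0738 with an estimated correlation). With a contrast of the 6 population means 2122 genes passed limma, and with population as a random block 288. Under that block 26 values of named genes kept their side of the threshold and 6 lost a call. The list tests had no such block. For thymus against bone marrow in the fit with 2 groups 476 genes passed limma, 289 higher and 187 lower in thymus, and 128 differed at least 2-fold. The count was 195 without LMPP replicate 1, 238 without LMPP replicate 2, 303 without CLP replicate 1, 189 without the DN2 array, 176 without DN3 replicate 1 and 184 without DN3 replicate 2.

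The last question was which genes were highest in 1 of the 5 replicated populations, with DN2 given as a value; the smallest of the 4 log2 differences from the other populations is called the margin. HSC had 118 such genes, led by Pf4 (10.96 ± 0.023, margin 5.43, adjusted p = 2.21e-07), Car1 and Cd55, an inhibitor of complement. CLP had 26, led by Ebf1 (margin 4.19), Blnk and Gimap4, a GTPase of lymphocytes, and also Siglech and Ly86, a partner of a Toll-like receptor homologue. ETP had 37: Fasl stood at 7.99 ± 0.069 (margin 3.70, adjusted p = 3.38e-06) and at 6.69 in DN2, and H2-Aa and Cd7 were among the others, with DN2 values of 6.02 and 7.42. Olfm5 was also among them (8.74 ± 0.083, margin 2.58) but stood higher in the DN2 array (9.51). A gene of this ETP set was therefore not always highest in ETP once DN2 was counted. The mast cell proteases Mcpt1 (6.50 ± 0.82) and Mcpt2 (6.23 ± 0.75) were among the ETP genes, at 3.82 and 3.71 in DN2, and Mcpt1 was not called without DN3 replicate 2 (adjusted p = 0.0577). DN3 had 199, led by Cd3d, Sh2d1a (margin 4.97) and Themis (4.92), and LMPP had 1, Wfdc17 (10.28 ± 0.29, margin 2.18), which was not called without CLP replicate 2 (adjusted p = 0.0692).

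The number of genes highest in HSC was 60 and 65 without LMPP replicates 2 and 1, 68 and 70 without ETP replicates 1 and 2, 73 without DN3 replicate 2 and 186 without HSC replicate 2. In CLP it was 17 and 14 without CLP replicates 1 and 2, 11 and 10 without LMPP replicates 1 and 2, 17 and 16 without ETP replicates 1 and 2, 14 and 13 without DN3 replicates 1 and 2, and 17 with each array centred on its median. In ETP it was 22 and 18 without ETP replicates 1 and 2, 21 and 20 without LMPP replicates 1 and 2, 19 and 20 without CLP replicates 1 and 2, 20 and 16 without DN3 replicates 1 and 2, and 22 without HSC replicate 1. The number of genes highest in DN3 was 112 and 98 without DN3 replicates 1 and 2 and 118 without ETP replicate 1, and in LMPP it was 2 without LMPP replicate 1.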

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

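All alternatives below were planned, and none reversed the direction of a called gene named in the text; the number of arrays and their signal over background limit the precision, and a population left with 1 array was assumed to vary like the others. The cause of the changes below was not tested, except that a stricter threshold leaves fewer calls by construction. Leaving out each array in turn gave these ranges of called genes: genes differing among the 6 populations (2430) 1499 to 2572, LMPP against HSC (586) 310 to 622, CLP against LMPP (228) 98 to 257, ETP against LMPP (460) 228 to 521, ETP against CLP (502) 248 to 543, DN2 against ETP (199) 92 to 200, DN3 against DN2 (358) 181 to 385, DN3 against ETP (1310) 695 to 1426 and thymus against bone marrow (476) 176 to 696. Genes highest in HSC (118) ranged from 60 to 186, in LMPP (1) from 0 to 2, in CLP (26) from 10 to 26, in ETP (37) from 16 to 37 and in DN3 (199) from 98 to 199. Lists passing camera ranged from 9 to 12 for LMPP against HSC (9), 11 to 17 for CLP against LMPP (15), 6 to 11 for ETP against LMPP (10), 11 to 12 for ETP against CLP (11), 12 to 13 for DN2 against ETP (12), 9 to 9 for DN3 against DN2 (9), 10 to 14 for DN3 against ETP (13) and 13 to 17 for the tissues (14).

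At adjusted p under 0.01 there were 1378 genes differing among the 6 populations, 280 for LMPP against HSC, 104 for CLP against LMPP, 213 for ETP against LMPP, 230 for ETP against CLP, 96 for DN2 against ETP, 191 for DN3 against DN2, 781 for DN3 against ETP and 78 for thymus against bone marrow, with 58 genes highest in HSC, 12 genes highest in CLP, 15 genes highest in ETP and 117 genes highest in DN3. At least 2-fold changes numbered 1437 among populations, 249 for LMPP against HSC, 136 for CLP against LMPP, 206 for ETP against LMPP, 255 for ETP against CLP, 594 for DN3 against ETP and 128 for the tissues. With 2 groups only in the fit, LMPP against HSC called 137 genes, CLP against LMPP 67, ETP against LMPP 195 and ETP against CLP 231; this was not run where DN2 enters. Array weights gave 2030 for DN3 against ETP and 850 for the tissues, centring on medians 17 genes highest in CLP, a contrast of 6 population means 2122 and population as a random block 288 (consensus correlation 0.157) for the tissues. With the correlation estimated for each list, 4, 3, 0, 0, 2, 1, 5 and 1 lists passed camera in the 8 comparisons (4, 8, 6, 7, 9, 4, 7 and 6 at unadjusted p under 0.05), and fry gave 8, 9, 8, 11, 8, 9, 14 and 8. Replicate number as a block gave 335 genes for the tissues and 155 for DN2 against ETP; deviations of arrays sharing a number correlated from -0.26 to 0.28 across genes over 10 pairs of groups, 4 above 0.1 and 3 below -0.1. Of the values of named genes, 4068 kept their side of the threshold when an array was left out, 524 lost a call and 5 gained one. With 2 groups only in the fit 195 kept their side and 85 lost a call. At adjusted p under 0.01 these numbers were 325 and 101, and at least 2-fold 350 and 76. With population as a random block for the tissues they were 26 and 6.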

Other observations

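The tests of cell handling, of array scaling, of HSC replicate 2, of macrophages and neutrophils apart and of whole populations in the splits, the mast cell list and the neighbouring genes named here were chosen only after the results they follow were seen.

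Lists with a smaller part in the comparisons gave these results, with member counts over all genes and then adjusted over the list alone. Stromal, epithelial and endothelial (0 of 22 called), DNA methylation and Polycomb (0 of 24), and E protein and Id genes (1 of 13 rose) were not called as lists by camera for LMPP against HSC, with adjusted p of 0.344, 0.523 and 0.936; adjusted over the list alone the counts were 0, 0, and 1 rose and 1 fell. Without HSC replicate 2, 4 stromal, epithelial and endothelial genes and 1 DNA methylation and Polycomb gene fell. The stromal, epithelial and endothelial list had called members elsewhere, although camera called it in no comparison. Pdgfrb (2.25-fold) and Ccl25 (1.6-fold) rose for ETP against LMPP, and Pdgfrb rose 2.57-fold for ETP against CLP. Epcam rose 4.67-fold and Pdgfrb fell 2.15-fold for DN3 against ETP.

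The list of 21 later thymocyte and mature T cell genes passed camera towards LMPP for LMPP against HSC (adjusted p = 2.49e-07, and adjusted p = 0.244 with an estimated correlation), where 6 rose and 1 fell (9 and 1 adjusted over the list alone), and 3 rose without HSC replicate 1 or LMPP replicate 2. It passed towards CLP for ETP against CLP (adjusted p = 7.28e-06, and adjusted p = 0.239 with an estimated correlation), where 5 fell and 1 rose (9 and 2 adjusted over the list alone); 3 fell without ETP replicate 1, and none rose without CLP replicate 2 or either ETP replicate. For DN3 against ETP 4 of 15 V(D)J recombination and end joining genes rose (4 adjusted over the list alone; adjusted p = 0.000554, and adjusted p = 0.17 with an estimated correlation) and 4 of 23 erythroid and megakaryocyte genes fell (4 adjusted over the list alone; adjusted p = 0.00158, and adjusted p = 0.158 with an estimated correlation).

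For DN2 against ETP 2 of 18 Hox genes and cofactors fell (3 adjusted over the list alone; adjusted p = 0.000512, and adjusted p = 0.118 with an estimated correlation), and 1 fell without either LMPP, ETP or DN3 replicate. Of 21 homing receptors and adhesion genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.00223, and adjusted p = 0.0971 with an estimated correlation); 1 fell without ETP replicate 2 or either DN3 replicate, and none rose without either ETP or DN3 replicate.

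For thymus against bone marrow 3 of 19 cell cycle inhibitors and quiescence genes fell (5 fell and 1 rose adjusted over the list alone; adjusted p = 0.00368, and adjusted p = 0.0738 with an estimated correlation); none fell without LMPP replicate 1, the DN2 array or DN3 replicate 1, and 1 fell without LMPP replicate 2, CLP replicate 1 or DN3 replicate 2. Of 16 imprinted genes 2 fell (2 fell and 1 rose adjusted over the list alone; adjusted p = 0.0198, and adjusted p = 0.372 with an estimated correlation); 1 fell without HSC replicate 1, either LMPP replicate, CLP replicate 1, ETP replicate 2, the DN2 array or either DN3 replicate, and 1 rose without HSC replicate 2. Of 18 macrophage genes 0 were called over all genes or adjusted over the list alone (1 fell without HSC replicate 1 or ETP replicate 2), although the list passed camera towards marrow (adjusted p = 0.0198, and adjusted p = 0.372 with an estimated correlation). For CLP against LMPP 0 of 16 glycolysis genes were called (4 fell and 1 rose adjusted over the list alone), although the list passed camera towards LMPP (adjusted p = 0.00172, and adjusted p = 0.253 with an estimated correlation), not so without LMPP replicate 2 (0.0523) or CLP replicate 1 (0.124).

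Neighbours in the RefSeq order had these levels, whose similarity was not tested. In HSC, LMPP, CLP, ETP, DN2 and DN3 in turn, Iftap stood at 4.95, 9.53, 10.82, 9.12, 9.48 and 10.58, Rag2 at 4.79, 7.72, 9.09, 7.33, 7.86 and 9.08, and Rag1 at 5.97, 7.39, 10.98, 7.05, 8.21 and 11.54, while Traf6 ranged from 6.65 to 7.35. Around Olfm5 (8.74 in ETP, 9.51 in DN2 and 6.03 in DN3), Olfr648 stood at 7.58 in ETP, 7.56 in DN2 and 4.09 in DN3, Olfr649 at 8.53, 8.49 and 4.57, Ubqlnl at 6.71, 6.85 and 4.91, Olfr644 at 6.12, 6.77 and 5.04, and Trim6 at 6.69, 6.39 and 5.92. Over the 6 populations Olfr645 ranged from 5.63 to 5.97, Olfr646 from 5.99 to 6.38 and Ubqln5 from 5.27 to 5.82.

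Cpa3, Mcpt1 and Mcpt2 were higher in ETP than in LMPP, Cpa3 31.8-fold (2 of 2 arrays). In HSC Cpa3 stood at 10.11, about its level in ETP, whereas Mcpt1 and Mcpt2 stood at 3.61 and 3.68. Mast cells or basophils in the ETP gate could bring other abundant transcripts of theirs. The median change of 13 such genes was 0.0626 (75th percentile 0.208, 0 of them called by limma), with Tpsb2 at 5.50 in ETP and 5.65 in LMPP. It was 0.125 over 16 genes with Cpa3, Mcpt1 and Mcpt2 included. Some of the 13 lay below the lower quartiles of the ETP arrays (4.81 and 4.77), such as Fcer1a at 3.94 and Mrgprb2 at 3.56. A low share of such cells, or a type lacking most of these transcripts, could leave the median unchanged. The list thus argues only against cells that carry most of the 13 transcripts, and other mast cells or basophils stay open. The macrophage list (18 genes, median -0.116, 75th percentile -0.0201, 0 called) argues only against a share of macrophages high enough to raise most of these genes. A low share of macrophages in the gate stays open. The median over 22 genes planned for neutrophils or macrophages was also -0.116, but 18 of them were macrophage genes; of 5 neutrophil genes S100a8 and S100a9 rose by 3.06 and 1.75 while Ngp, Camp and Lyz2 changed by -0.14, 0.01 and -0.45 (median 0.00504), so neutrophils in the gate stay open. Expression of the 3 proteases by ETP themselves may be the source and was not tested.

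Immediate early and stress genes were lower in ETP than in LMPP (median -0.641). Quantile normalization once more moved the number of genes called in this comparison from 460 to 523. The list median was then -0.725 (75th percentile -0.356, camera adjusted p = 1.42e-16, and 0.0794 with an estimated correlation). RMA had already normalized quantiles, so this second pass was a weak test of scaling. The median change of all genes was -0.0285 as deposited, so the deposited arrays were not shifted as a whole. RMA makes array distributions alike, so that median cannot decide whether scaling before or within RMA had a part. Cell handling that differed between thymus and marrow may be the cause: 5 of 5 thymic arrays had a list median below that of every marrow array (-0.476 to -0.298 against 0.142 to 0.39). Tissue, stage and handling coincide, so a difference between the cells in life stays open and was not tested.

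Of 23 erythroid and megakaryocyte genes 10 were called higher in HSC than in LMPP (5 without LMPP replicate 1, 4 without LMPP replicate 2). Over all 23 the median of HSC replicate 2 lay 0.506 above the LMPP mean (25th percentile -0.0504) and that of HSC replicate 1 0.507 above it. Without HSC replicate 1 the list was still called (adjusted p = 5.42e-09; 0.0651 with an estimated correlation) and 4 members passed, which argues against committed progenitors in HSC replicate 1 alone as the source of the list's difference, but leaves that open for single genes. Committed progenitors in both HSC arrays, or expression of these genes by HSC, could each give the pattern, and neither was tested.

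Of 100 splits of the 11 arrays into 6 and 5, drawn from 462, 1 gave as many called genes as thymus against bone marrow, which was the real split itself (476 genes; highest other 1). Most of the drawn splits parted the 2 arrays of at least 1 population, which turns differences between populations into spread. Their low counts therefore cannot decide whether tissue sets the real split apart. Splits that keep each population whole number 10, too few for a share under 0.05; the real one gave 476 genes and the highest other 234, with HSC, DN2 and DN3 on one side.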
